A study of Homo sapiens with 6 samples.

How the data were processed

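Total RNA from PC3-ML cells treated for 24 h with DMSO or with 500 nM PD 0332991 was measured on 6 Affymetrix human transcriptome arrays, 3 per group. Per the labels' protocols, the cells were grown in DMEM with serum, RNA was extracted with a column kit and biotinylated cDNA was made with a NuGEN whole transcriptome amplification system, while another label names an Affymetrix WT Plus kit; which of these was used could not be settled. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

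The authors deposited 1 value per array and transcript cluster, which lies on a log2 scale judging by the range of the values, from 2.04 to 19.93. The log base is not stated; 2 to the power of the highest value is 999966. Expression Console was used, per the submitters' processing notes, without a version; background correction, normalization and summarisation methods were not given in the sources used here. Array medians over all clusters differed slightly, from 4.48 to 4.56, which does not show what normalization had been applied. No further normalization was applied in the main comparison. On each array 37 to 41 clusters lay within 0.5 of its highest value, and 3 of the genes tested did so on every array; no such gene passed the threshold.

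The table held 65535 transcript clusters, which with its header fills the row limit of an older spreadsheet (65536 lines) and ends within chromosome 22, so genes beyond that point were not analysed here. Gene symbols came from the array's annotation table: 22685 clusters named 1 gene, 1385 named several and 41465 were unnamed here. Symbols were updated through Entrez identifiers, which matched for 20487 of the single-gene clusters; the other 2198 kept the annotation's symbol. Clusters with several or no symbols were left out of the comparison and of the gene lists. Of 296 genes with more than 1 cluster, the brightest cluster by its mean over all arrays was kept, which left 22375 genes. No minimum level was set. No genome build is printed and no genome positions were used here.

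Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with 1 mean per group, empirical Bayes moderation, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of an adjusted p under 0.05. Intervals at 95% of single genes use the moderated spread. The verbs rose and fell are used for genes past this threshold. Beyond that, 23 gene lists were fixed before the data were examined, 6 of them primary (replication, nucleotide synthesis, G1/S regulators, mitosis, repair and histones), and tested with camera, of limma, with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 23 lists. Because genes of a list vary together, camera was also run with the correlation estimated per list, and fry was run as another test. With the preset correlation 12 of the 23 lists were called, 7 lower and 5 higher, and with the estimated correlation 3 were (replication, mitosis and histones). For each list, members past the threshold over all genes and adjusted over the list alone were counted, and list means per array were compared by a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3. Differences between the changes of a pair of genes were tested by the same permutation, with 95% intervals from a linear model on the difference of both genes on each array; these pairs were chosen after their values were seen.

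Named genes followed a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among genes past the threshold with no overlap between the groups, 18 genes chosen for their role whatever their values, and in each list the 4 members with the smallest p, with all members past the threshold where 5 or fewer were. Of the 18, 17 were tested; CDKN2C was not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

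The limma and camera steps were tested on simulated data with the real genes' means and spreads. For the comparison of PD 0332991 with DMSO, over 22375 genes of which 200 were changed, 10 of 50 genes changed by 0.25 on the log2 scale were recovered, 38 of 50 at 0.5, 48 of 50 at 1 and 50 of 50 at 2, and 13 unchanged genes were called. Small changes were therefore often missed in this simulation with 3 arrays per group. Only 200 genes were changed there, while 2531 passed the threshold in the real data. The adjustment was therefore stricter in the simulation, and the share of small changes missed in the real data is not known. A list moved by 0.5 was called, and 0 of the others were. Because noise was drawn separately for each gene, this does not test false calls of lists whose genes vary together. In the real data the estimated correlation within a list reached 0.37 (hypoxia and glycolysis).

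Alternatives tried were the replicate number as a block, a variance trend with a robust prior, array quality weights, quantile normalization, median centring, a filter keeping genes above the median level, the mean of a gene's clusters, all 65535 clusters, a change of at least 1.5-fold, an adjusted p under 0.01, leaving out each array in turn, and leaving out genes at the ceiling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.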

Results

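Gene expression was measured on 6 microarrays of total RNA from PC3-ML cells, a metastatic derivative of the PC-3 human prostate cancer cell line. Of the samples, 3 had received the DMSO vehicle and 3 had received 500 nM PD 0332991 for 24 h. PD 0332991, also known as palbociclib, inhibits the cyclin-dependent kinases CDK4 and CDK6, which phosphorylate the retinoblastoma protein and so release E2F transcription factors at the entry into S phase. The series title frames the treatment as a way of re-activating the retinoblastoma protein, and the comparison asks which transcripts differ after a day of kinase inhibition. The 6 arrays had similar medians over the 22375 genes tested, from 5.33 to 5.37 on the log2 scale. Across genes, which are not independent replicates, Pearson correlations were 0.9977 to 0.9985 between arrays of the same group and 0.9938 to 0.9948 between arrays of different groups. The number of arrays, 3 per group, limits the precision of each value.

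Genes of the cell division cycle were lower with PD 0332991, and the falls were the largest changes measured. MKI67, which encodes the proliferation marker Ki-67, went from 12.28 ± 0.016 with DMSO to 7.80 ± 0.072 with PD 0332991 (log2 expression, mean ± SD, n = 3), a level 22.4-fold lower. Of the fixed mitotic genes, 61 of 62 measured fell, and of the fixed replication genes 43 of 44. Increases were smaller, and the 12 largest included OAS2, IFI44L and SAMD9L, genes induced by interferons, with OAS2 2.60-fold higher. Of 36 interferon-stimulated genes measured, 21 rose and none fell; 12 rose without DMSO 2 or without DMSO 3, and the list had an adjusted p = 0.138 with an estimated correlation.

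In total, 2531 of 22375 genes (11.3%) had a limma adjusted p under 0.05, 1247 of them higher and 1284 lower with PD 0332991. All 2531 had no overlap between the 3 DMSO and the 3 PD 0332991 values. Over all genes tested, 6679 (29.9%) had no overlap, against 10% given by chance for 3 against 3. Sizes differed between the directions: 192 genes fell by at least 2-fold and 10 rose by as much, and 69 fell by at least 4-fold against 0 that rose as far. The median log2 change was 0.32 among the genes that rose and -0.40 among those that fell. With any single array left out, between 1602 and 1857 genes passed the threshold, of which 716 to 815 were higher.

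**Figure D1:**
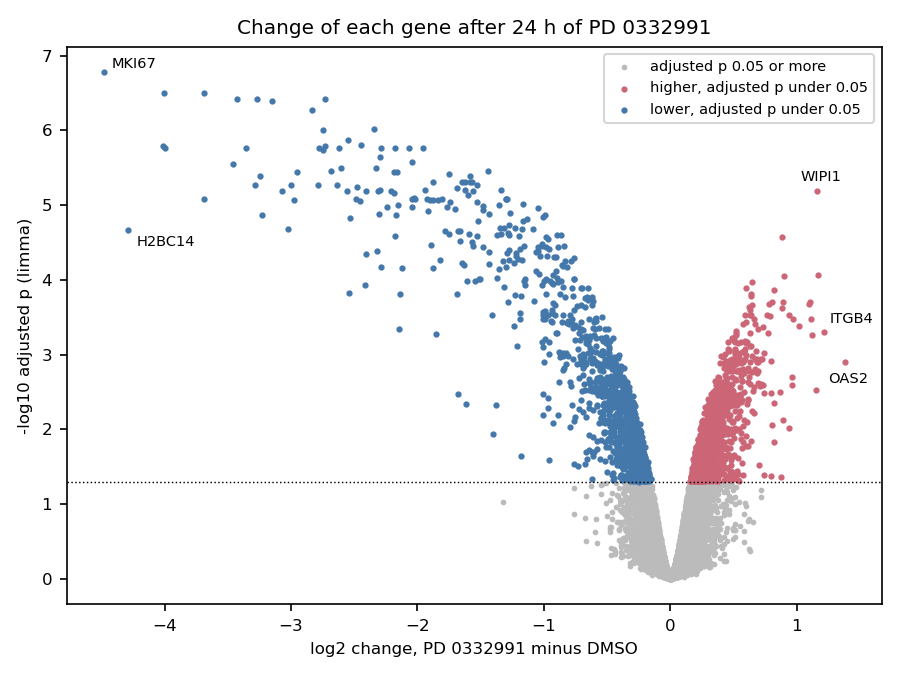
Log2 change of each of 22375 genes (PD 0332991 minus DMSO, horizontal axis) against the negative log10 of its limma adjusted p (vertical axis), with 1 point per gene and a dotted line at an adjusted p of 0.05. The falls reach -4.48 (MKI67) and the rises 1.38 (OAS2).

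After MKI67, the largest falls were those of the histone gene H2BC14 (log2 change ± SE, -4.29 ± 0.190) and of FAM111B (-4.02 ± 0.091). KIF20A, a mitotic kinesin, went from 11.23 ± 0.043 to 7.23 ± 0.088 (log2 expression, mean ± SD, n = 3), and TOP2A, the DNA topoisomerase that untangles chromosomes, from 12.83 ± 0.117 to 8.83 ± 0.157. The spindle gene NUSAP1 and the histone gene H2AC21 were both 12.9-fold lower, and the linker histone H1-4 had a log2 change of -3.46. The rest of the 12 largest falls were those of cyclin A2 (CCNA2, 10.7-fold), the spindle gene DLGAP5 (10.3-fold), WDR76 (9.74-fold) and the mitotic kinase CDK1 (9.64-fold). Adjusted p-values of these 12 genes lay between 1.68e-07 and 2.14e-05. Among the rises, OAS2, an antiviral enzyme, went up by 1.38 ± 0.139 on the log2 scale. It was followed by the integrin subunit ITGB4 (2.32-fold), the organic anion transporter ABCC3 (2.24-fold) and WIPI1, which acts in autophagosome formation (2.23-fold, log2 change 1.16 ± 0.040, adjusted p = 6.58e-06). IFI44L was 2.22-fold higher, the pentraxin PTX3 2.18-fold, AGR2 2.17-fold, the collagenase MMP13 2.16-fold, AHNAK2 2.14-fold and FKBP14 2.03-fold. EHD3 and SAMD9L, at 1.96-fold and 1.95-fold, completed the 12 largest rises.

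Members of the pathway that the drug acts on did not move together. CDK4 went from 12.46 ± 0.127 to 11.82 ± 0.125 (log2 expression, mean ± SD, n = 3), 1.56-fold lower (adjusted p = 0.00448), while the log2 change of CDK6 was 0.07 ± 0.057 (adjusted p = 0.555). The difference between these changes, CDK4 minus CDK6, was -0.71 (95% interval -0.92 to -0.49, exact permutation p = 0.1, the smallest possible with 3 against 3). Cyclin D1 (CCND1) was 1.30-fold higher (adjusted p = 0.0138), and cyclin D3 (CCND3) had a change of -0.15 (adjusted p = 0.0638). RB1, which encodes the retinoblastoma protein, was 1.27-fold lower (adjusted p = 0.00574), and its relative RBL1, encoding p107, was 2.56-fold lower (adjusted p = 7.28e-05). RB1 minus RBL1 came to 1.01 (95% interval 0.80 to 1.22, exact permutation p = 0.1). RBL2, encoding p130, had a change of 0.13 (adjusted p = 0.177). Cyclin E2 (CCNE2) was 7.98-fold lower, from 8.18 ± 0.174 to 5.18 ± 0.092, whereas cyclin E1 (CCNE1) had a change of -0.01 ± 0.043 (adjusted p = 0.900). CCNE1 minus CCNE2 was 2.98 (95% interval 2.61 to 3.35, exact permutation p = 0.1). E2F1 was 1.54-fold lower (adjusted p = 0.00272), and E2F2 had a change of -0.26 (adjusted p = 0.0302). The calls of CCND1 and E2F2 were lost when some single arrays were left out: CCND1 had an adjusted p of 0.0508 without DMSO 1 and 0.0520 without DMSO 3, and that of E2F2 ranged up to 0.0901 and passed 0.05 without DMSO 1, DMSO 2, PD 0332991 replicate 1 or PD 0332991 replicate 3.

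**Figure D2:**
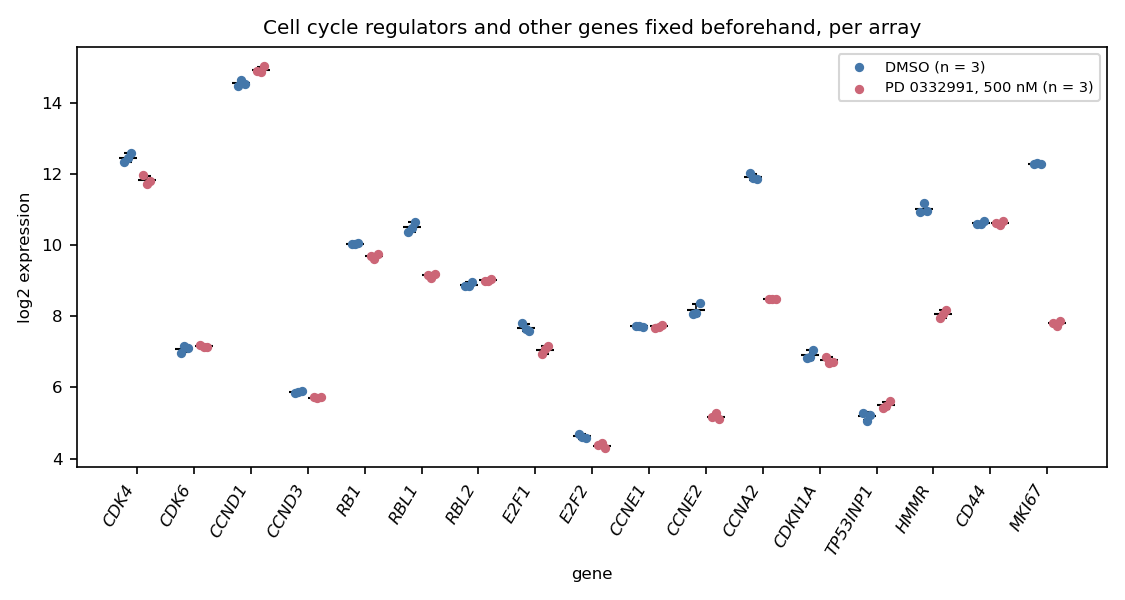
Log2 expression on each array (vertical axis) of the 17 genes fixed beforehand that were tested (horizontal axis), for DMSO and 500 nM PD 0332991 at 24 h; points are arrays, horizontal marks are group means and bars are SDs (n = 3). MKI67, CCNA2, CCNE2 and HMMR show the widest gaps between groups, and levels of different genes are not on a common scale.

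As a group, regulators of the G1 to S phase transition (E2F factors, retinoblastoma family, cyclins D and E and their kinases and inhibitors) were lower: of 29 measured, 14 fell, 1 rose and 14 did not pass the threshold, and adjusted over the list alone 15 fell and 2 rose. Next to CCNE2, the members with the smallest p were CDK2, the kinase partner of cyclins E and A (log2 change -1.43), the repressor E2F8 (-1.89) and the phosphatase CDC25A (-1.32). CCND1 was the member that rose. CDKN1A, encoding the kinase inhibitor p21, had a change of -0.15 (adjusted p = 0.339). The list was lower by camera (median log2 change -0.15, mean -0.49, adjusted p = 7.62e-09), with an adjusted p = 0.0782 with an estimated correlation.

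Genes of the DNA replication machinery fell almost without exception, 43 of 44 measured, also when adjusted over the list alone, with a median 2.01-fold lower. Log2 changes of the members with the smallest p were -3.07 for the primase subunit PRIM1, -2.73 for the checkpoint mediator CLSPN, -1.92 for the GINS complex subunit GINS2 and -1.65 for MCM10. GINS4, chosen after its value was seen, was the member that did not pass, with a change of 0.00 (adjusted p = 0.992). Among nucleotide synthesis genes, 11 of 18 measured fell, none rose and 7 did not pass, while 15 fell when adjusted over the list alone. The ribonucleotide reductase subunit RRM2 was 9.50-fold lower, thymidylate synthase (TYMS) 6.70-fold, thymidine kinase (TK1) 3.00-fold and GMPS, of guanine nucleotide synthesis, 1.87-fold. Homologous recombination and DNA repair genes fell in 22 of 25 cases, also when adjusted over the list alone, with none higher and 3 not past. Here log2 changes were -2.41 for the nuclease EXO1, -2.34 for the helicase BRIP1, -2.02 for RAD51AP1 and -1.53 for the chromatin remodeller HELLS. All 3 lists were lower by camera, with adjusted p = 9.01e-55 for replication, 1.63e-15 for nucleotide synthesis and 7.36e-29 for repair. The replication list remained past the threshold with an estimated correlation (adjusted p = 0.0203), while nucleotide synthesis had an adjusted p = 0.0746 with an estimated correlation and repair an adjusted p = 0.0628 with an estimated correlation.

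Mitotic genes showed the largest shift of any of the 23 lists, with 61 of 62 measured lower, also when adjusted over the list alone, and a median log2 change of -2.04 (4.10-fold lower). Besides MKI67, KIF20A and NUSAP1, CDK1 (-3.27) and CCNA2 (-3.43) were among the members that fell. CDC25B, chosen after its value was seen, had a change of 0.14 (adjusted p = 0.0977); it was counted as higher when adjusted over the list alone. Camera gave an adjusted p = 1.38e-92 for the list, and 0.0203 with an estimated correlation. Of the replication-dependent histone genes, whose transcripts accumulate in S phase, 22 of the 51 fixed were tested; 18 fell, 1 rose and 3 did not pass, and 19 fell and 1 rose when adjusted over the list alone. The falls included H1-4 (-3.46), H2BC17 (-3.23), H2BC11 (-3.02) and HIST1H2AH (-2.56), and the rise was that of H2AC6 (0.43, adjusted p = 0.00408; chosen after its value was seen). This list was lower by camera with an adjusted p = 3.35e-20, and 0.0123 with an estimated correlation. Histone genes have near-identical copies, so the value of a single histone gene is uncertain. List means per array separated the groups for each of these 6 lists (exact permutation p = 0.1, the smallest possible).

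**Figure D3:**
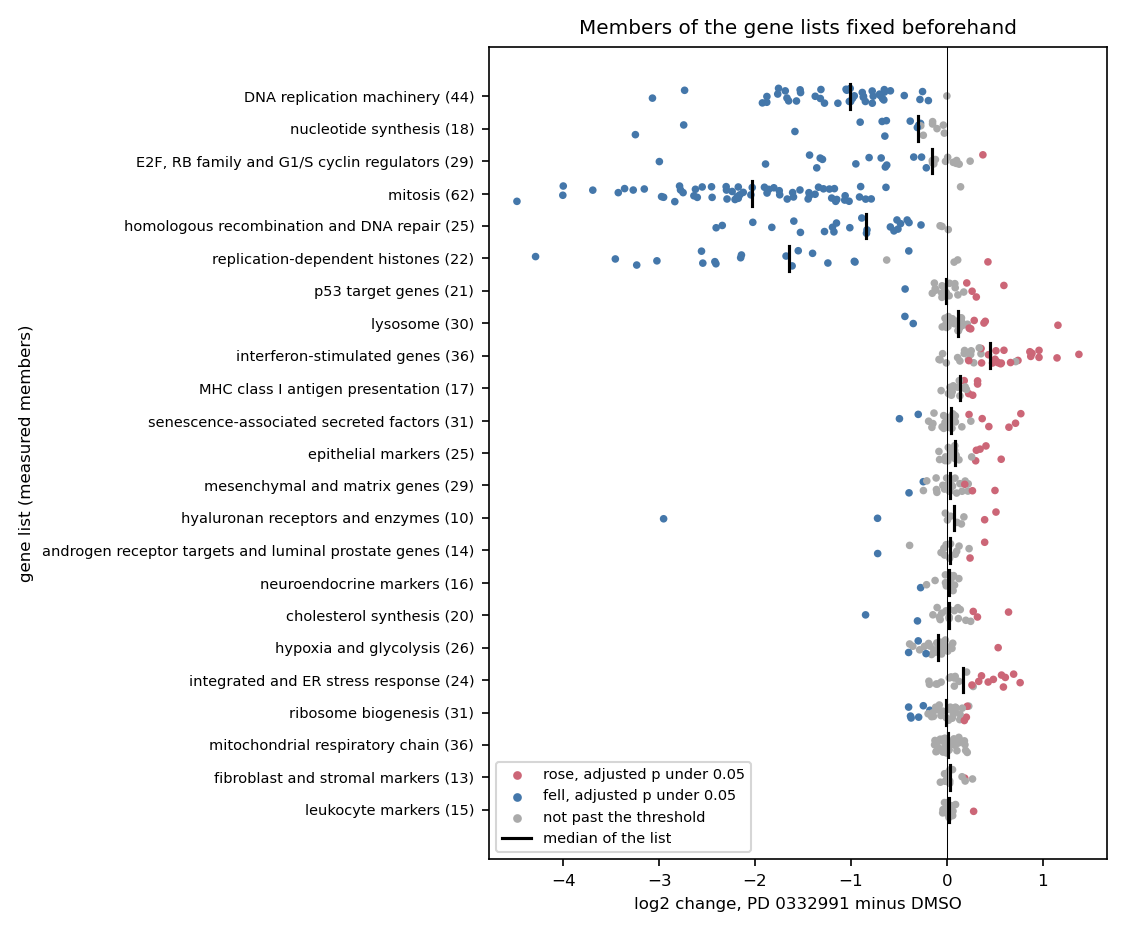
Log2 change (PD 0332991 minus DMSO, horizontal axis) of each measured member of the 23 gene lists fixed beforehand (vertical axis, number of measured members in parentheses); each point is a gene, coloured by whether it rose, fell or did not pass an adjusted p of 0.05, and the black line is the list's median. Mitosis (-2.04) and replication-dependent histones (-1.64) have the lowest medians and interferon-stimulated genes (0.46) the highest.

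Interferon-stimulated genes rose in 21 of 36 cases measured and fell in none, and 28 rose when adjusted over the list alone. The median log2 change was 0.46 (1.37-fold). OAS2 rose by 1.38 on the log2 scale, IFI44 by 0.56, PARP14 by 0.52 and IFITM1 by 0.44; IRF1, a transcription factor, had a change of -0.0048 (adjusted p = 0.966; chosen after its value was seen). Camera placed the list higher than other genes (adjusted p = 4.68e-13), with an adjusted p = 0.138 with an estimated correlation. Leaving out DMSO 2 or DMSO 3 lowered the number that rose from 21 to 12 in each case. Of the 17 genes of MHC class I antigen presentation measured, 5 rose and none fell, with 8 higher when adjusted over the list alone. These were the peptide transporter TAP1 (0.32), tapasin (TAPBP, 0.32), HLA-E (0.27), HLA-B (0.23) and HLA-F (0.18), of which the HLA genes are close relatives that probes may not fully separate. The list was higher by camera (median 0.14, adjusted p = 0.000197), with an adjusted p = 0.0782 with an estimated correlation, and with any single array left out 2 of its members passed. Leukocyte markers, measured beside these lists, had a median change of 0.02, and 1 of 15, CD68, rose (0.28, adjusted p = 0.0302).

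Genes of the integrated and ER stress response rose in 10 of 24 cases and fell in none, with 11 higher and 2 lower when adjusted over the list alone. HERPUD1, of ER-associated degradation, rose by 0.77, the ER chaperone HSPA5 by 0.70, CTH by 0.61 and the cystine transporter SLC7A11 by 0.59 on the log2 scale. ATF4 and DDIT3, transcription factors of the response chosen after their values were seen, had changes of -0.19 (adjusted p = 0.0865) and 0.13 (adjusted p = 0.308). Camera gave an adjusted p = 0.000262 for the list (median 0.17), with an adjusted p = 0.0749 with an estimated correlation. Lysosomal genes rose in 6 and fell in 2 of 30 cases, or 10 and 2 when adjusted over the list alone. WIPI1 (1.16) and the mannosidase MAN2B1 (0.40) were among those that rose, and the cholesterol exporter NPC1 (-0.44) and the glucuronidase GUSB (-0.35) were those that fell. The list's median was 0.12 (camera adjusted p = 0.00119), with an adjusted p = 0.341 with an estimated correlation, and 3 members rose when DMSO 3 was left out. Epithelial markers rose in 5 of 25 cases and fell in none, 6 being higher when adjusted over the list alone. They were CLDN1 (0.57), KRT19 (0.41), JUP (0.35), KRT8 (0.31) and KRT7 (0.30), proteins of tight junctions, desmosomes and the keratin skeleton. E-cadherin (CDH1), chosen after its value was seen, had a change of 0.08 (adjusted p = 0.326). The epithelial list had a median of 0.08 (camera adjusted p = 0.00396) and an adjusted p = 0.0946 with an estimated correlation. Hypoxia and glycolysis genes were lower as a list (median -0.10, camera adjusted p = 0.000381), with an adjusted p = 0.459 with an estimated correlation. Only 4 of the 26 passed on their own over all genes tested: KDM3A (-0.40), PGAM1 (-0.30) and TPI1 (-0.22) fell and ALDOC rose (0.54), and adjusted over the list alone 4 fell and 1 rose. The DMSO arrays were spread on this list, with means of 0.14, 0.05 and -0.03 relative to each gene's mean over all arrays, and 1 gene fell when DMSO 1, DMSO 2, PD 0332991 replicate 1 or PD 0332991 replicate 2 was left out.

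In the remaining 11 lists camera's adjusted p did not pass the threshold. Of 21 p53 target genes, 4 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone. ZMAT3 (0.60), TP53INP1 (0.31), RRM2B (0.26) and TIGAR (0.21) rose and DDB2 (-0.43) fell, with a list median of -0.01 against a mean of 0.04 (adjusted p = 0.664). TP53INP1, at an adjusted p of 0.0471, passed 0.05 with no array left out and failed it whichever array was left out, with values from 0.0562 to 0.118, and 1 or 2 of the p53 targets rose with any array left out. Senescence-associated secreted factors rose in 6 and fell in 2 of 31 cases, or 7 and 3 when adjusted over the list alone. IGFBP5 (0.77), CCL20 (0.72) and IL1B (0.65) rose and the urokinase receptor PLAUR (-0.49) fell, while the median was 0.05 (adjusted p = 0.267). IL6, chosen after its value was seen, had a change of 0.05 (adjusted p = 0.619).

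Mesenchymal and matrix genes rose in 3 and fell in 2 of 29 cases, or 4 and 4 when adjusted over the list alone. CCN2 (0.50), CCN1 (0.27) and COL1A1 (0.19) rose, and AXL (-0.39) and vimentin (VIM, -0.24) fell (list median 0.03, adjusted p = 0.606). Leaving out any DMSO array left 1 gene of that list higher, and none fell without DMSO 2 or PD 0332991 replicate 2. Among 10 hyaluronan receptors and enzymes, the motility receptor HMMR, also a member of the mitotic list, was 7.74-fold lower (11.02 ± 0.137 to 8.07 ± 0.106, adjusted p = 3.67e-06), and the synthase HAS2 fell by 0.72 on the log2 scale. TNFAIP6 (0.51) and the hyaluronidase CEMIP (0.40) rose, so that 2 rose and 2 fell, or 3 and 2 when adjusted over the list alone. CD44, the main hyaluronan receptor, had a change of 0.01 ± 0.050 (adjusted p = 0.956). The list's median was 0.07 and its mean -0.23, and camera found no shift (adjusted p = 0.647). Androgen receptor targets and luminal prostate genes rose in 2 and fell in 1 of 14 cases (4 and 2 when adjusted over the list alone): STEAP2 (0.40) and ELL2 (0.24) were higher and FKBP5 (-0.72) lower, and HOXB13 had a change of 0.23 (adjusted p = 0.0780; list median 0.03, adjusted p = 0.606). Of 16 neuroendocrine markers, ENO2 fell (-0.27), also when adjusted over the list alone, a call kept only when DMSO 3 was the array left out, and SCG5 had a change of -0.21 (adjusted p = 0.0743). The neuroendocrine median was 0.02, its mean -0.01 and its adjusted p = 0.795. Only 1 of the 16 lay above the median level of all genes, so small changes of the others would be hard to see. Cholesterol synthesis genes rose in 3 cases and fell in 2 of 20, or 4 and 2 when adjusted over the list alone, with ACAT2 (-0.85) and FDPS (-0.31) lower and TM7SF2 (0.64), MSMO1 (0.32) and SC5D (0.28) higher (list median 0.03, adjusted p = 0.664). Without DMSO 1, DMSO 2, PD 0332991 replicate 1 or PD 0332991 replicate 3, 1 cholesterol gene rose.

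Ribosome biogenesis genes fell in 6 and rose in 3 of 31 cases, or 6 and 4 when adjusted over the list alone. NOP58 (-0.40), fibrillarin (FBL, -0.38), the RNA polymerase I factor UBTF (-0.37) and RRP1B (-0.24) were among those that fell. The list's median was -0.01 and its mean -0.04 (adjusted p = 0.267), and after quantile normalization its direction by camera turned to higher (adjusted p = 0.973). With single arrays left out 0 or 1 of its genes rose and 3 to 5 fell. None of 36 mitochondrial respiratory chain genes passed limma's adjusted threshold, nor when adjusted over the list alone; NDUFB5 had a change of 0.21 (adjusted p = 0.0750) and the median was 0.01 (camera adjusted p = 0.636). That list was higher after quantile normalization (adjusted p = 0.0179). Fibroblast and stromal markers, tested as a sign of other cells, had a median of 0.03 (adjusted p = 0.285); COL1A1 rose, and none of the 13 did when adjusted over the list alone or with any array left out. S100A4 and SPARC, the next by p, had changes of 0.16 (adjusted p = 0.0727) and 0.19 (adjusted p = 0.110). With genes above the median level only, 4 of the 13 fibroblast and stromal markers were kept and 3 rose (median 0.17). The others were dim, where a small change would be hard to see. Leukocyte markers other than CD68 did not pass, CD14 having a change of 0.09 (adjusted p = 0.304), and 1 of the 15 rose when adjusted over the list alone (list adjusted p = 0.656), but none did without DMSO 2, DMSO 3, PD 0332991 replicate 2 or PD 0332991 replicate 3. The direction of the leukocyte list turned to lower after quantile normalization (adjusted p = 0.973).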

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

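The tests in this part come from the planned comparison of all transcript clusters of the table, and none was chosen after the result was seen. Clusters outside the comparison of named genes also held differences between DMSO and PD 0332991. Of 41465 clusters that were unnamed here, 417 passed the threshold, 186 higher and 231 lower, with log2 changes from -3.90 to 1.57. Of 1385 clusters that name several genes, 78 passed, 18 higher and 60 lower. Among those that fell were clusters naming the histone genes H2AC4 and H2AC8 (log2 changes of -3.73 and -4.28) and a cluster naming RRM1 and LINC02749 (-1.41), given here as examples chosen after their values were seen.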

How the results depend on the processing

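Leaving out genes at the ceiling was the alternative chosen after seeing the data; the others were listed before the data were examined. Of the changed genes (2531, with 1247 higher and 1284 lower), none shared with any alternative's calls turned its direction. Counts with any single array left out were 1602 to 1857 changed, 716 to 815 higher and 886 to 1042 lower. Testing all clusters gave 1482 changed and 547 higher, a 1.5-fold minimum 473 changed, 96 higher and 377 lower, and an adjusted p under 0.01 gave 1175, 458 and 717. With the replicate block 1740 genes were changed, 786 of them higher, and fewer residual degrees of freedom go with that design. Deviations of same-numbered arrays from each gene's group mean had correlations of 0.02, -0.01 and 0.04. Not every array's deviations correlated best with those of its own number, so the samples share only a number and no pairing was taken from it. Keeping genes above the median level gave 3312 changed from 11187 tested. The share of higher genes among the changed was 49.3% in the main comparison, 58.3% after quantile normalization and 41.6% after median centring. Among list shifts, 344 alternatives kept their direction and side of the threshold, 10 lost and 4 gained it, and 7 reversed. With estimated correlations 3 lists were called and these were not: nucleotide synthesis (adjusted p = 0.0746), G1/S regulators (0.0782), repair (0.0628), lysosome (0.341), interferon-stimulated genes (0.138), MHC class I (0.0782), epithelial markers (0.0946), hypoxia (0.459) and the stress response (0.0749). Quantile normalization reversed ribosome biogenesis and leukocyte markers (adjusted p = 0.973 for both) and called the respiratory chain (0.0179). By fry, which does not compare a list with other genes, 15 lists were called, among them senescence factors (adjusted p = 0.0167), androgen receptor targets (0.0120), fibroblast markers (0.0120) and hyaluronan genes, now lower (0.0285), while hypoxia was not (0.133) and neuroendocrine markers turned to higher (0.978). Single left-out arrays reversed uncalled lists: neuroendocrine markers had adjusted p-values of 0.445 to 0.925 and the respiratory chain 0.284 to 0.958. Mean log2 changes of lists moved by more than the spread between arrays after median centring for MHC class I (0.124) and epithelial markers (0.0977), and with genes above the median level only for G1/S regulators (-0.536), histones (-2.06), epithelial markers (0.156) and the stress response (0.251). Of single genes, CCNE1 had changes of 0.0051 after quantile normalization and -0.038 to 0.0017 with an array left out, and CD44 had -0.013 after median centring, -0.11 as the mean of its clusters and -0.024 to 0.039 with an array left out; neither was called in any of these. E2F2 lost its call under the block (adjusted p = 0.0515, range over alternatives 0.0153 to 0.0901). CCND3, not past the threshold in the main comparison (adjusted p = 0.0638), passed it with genes above the median level only (0.0306), at the same log2 change of -0.148, and in none of the other 13 alternatives. TP53INP1 kept its call in 4 of 13 alternatives (0.0411 to 0.118). Apart from the smaller sets of genes or arrays in some alternatives, the cause was not tested. No signal over background was used here, so it is unknown for dim genes whether a small change was measurable.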

Other observations

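The leukocyte test given here was chosen only after the result it bears on was seen, and the list of ER-to-Golgi transport genes was drawn up after 5 of its members had been seen among the called genes.

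Of 43 genes of transport between the endoplasmic reticulum and the Golgi measured, 25 rose with PD 0332991, none fell and 18 did not pass the threshold, with a median log2 change of 0.26. Those that rose include genes of the COPI coat (COPG1 0.78, COPB2 0.60, COPA 0.57), the COPII coat (SEC31A 0.59, SEC23B 0.54, SEC24D 0.53) and the retrieval and cargo receptors (KDELR3 0.82, TMED10 0.39), while TMED9 (0.04), TFG (-0.03) and COPG2 (-0.24) did not pass the threshold. The list also counts transcription factors: CREB3L2, which rose (0.37), and CREB3L1, which did not pass (0.05). These genes were chosen after their values were seen.

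The members seen beforehand do not alone account for the list's rise, since the others were also higher. Measured on the same arrays, those others may vary together with the seen members and are not an independent test of the choice. The 38 that had not been seen had a median of 0.234 (95% bootstrap interval over genes 0.142 to 0.318), and 20 of them rose. Camera's unadjusted p for these 38 was 1.61e-12, and 0.00958 with an estimated correlation. Adjusted only over the lists added to the fixed ones, these values became 3.23e-12 and 0.0192. The added lists are fewer than the fixed lists, so 0.0192 cannot be compared with the fixed lists' adjusted p-values. Whether these 38 would pass with an estimated correlation when adjusted together with the fixed lists was not tested. A difference between array medians, which lay between 5.33 and 5.37 over the genes tested, is too small to account for the list's rise. The median after centring was 0.214 (0.122 to 0.298 over genes). Centring could change it only slightly, so other kinds of array scaling stay untested for these genes. No biological explanation was tested for these genes.

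Interferon-stimulated genes were higher with PD 0332991 by camera with the preset correlation (mean log2 change 0.47), with an adjusted p = 0.138 with an estimated correlation, and the 21 that rose became 12 without DMSO 2 or without DMSO 3. A difference between array medians, which lay between 5.33 and 5.37 over the genes tested, is too small to account for the list's rise. The mean was 0.452 after median centring. Centring could move it only slightly and does not test other kinds of array scaling. After quantile normalization across arrays, 21 of the 36 measured still rose, with a median log2 change of 0.469. A single deviating array is argued against by a lowest mean of 0.437 with any array left out. Leukocyte RNA was not settled by its list, though the samples were of a cultured cell line. The leukocyte list's median was 0.0229 (95% bootstrap interval over its genes -0.02 to 0.06), under the bound set for it. However, 14 of its 15 genes lie under the median level of all genes, where a small rise would be hard to see. The member above it, CD68, rose (0.28, limma adjusted p = 0.0302). CD68 stood at 11.33 with DMSO against a list median of 3.99, so its rise alone does not point to leukocytes. Loss of DNA methylation was not measured. The maintenance methyltransferase DNMT1, chosen after its value was seen, fell by 1.02 ± 0.049 on the log2 scale (limma adjusted p = 3.29e-05). DNMT1 is a member of the replication list, of which 43 of 44 fell, so its fall is not separate evidence of lost methylation. Germline genes that promoter methylation silences had a median of 0.0405 (0.009 to 0.057 over genes), under the bound of 0.1 set beforehand. As 30 of the 36 also lie under the median level, loss of methylation stays open as well. None of 10 interferon ligands passed limma's adjusted threshold, with changes from -0.16 to 0.19, but the upper 95% bound reached 0.638 (IFNB1, chosen after its value was seen), so an induced ligand stays open too.

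Falls were larger than rises: the 100 largest falls averaged 2.41 on the log2 scale and the 100 largest rises 0.752, a ratio of 3.20. A ceiling of the signal that hides rises is argued against by a ratio of 3.08 (3.01 to 3.15 with an array left out) among 6549 genes with a DMSO mean between 7 and 12. The ratio was 3.00 after quantile normalization, so remaining differences between the arrays' distributions of values do not account for it. With array medians between 5.33 and 5.37 over the genes tested, this step could change the ratio only slightly. Other kinds of array scaling stay untested. No biological explanation was tested for this difference.

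Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 2531 genes, and the highest number from another split was 0. Every other split puts treated and DMSO arrays in the same group. The treatment's difference then adds to the spread within groups, which lowers the number of genes called. The 0 genes of the other splits therefore do not show how many would be called by chance, and no conclusion is drawn from them. For the gene lists the real split called 12 and the highest other split 9, so 1 of the 10 was as large. There too the other splits still hold part of the real difference. With 10 splits a share under 0.05 cannot be reached.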
